A study of Homo sapiens with 120 samples.

How the data were processed

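RNA was measured by sequencing in 120 libraries from 7 established human breast cancer cell lines: BT20, BT549, HCC1419, HCC1806, HS578T, MCF7 and T47D. Per the labels' protocols, cells were seeded in 12-well plates, received the drug 24 h later, and were lysed 6 or 24 h after that; 500 ng of total RNA went into a stranded poly(A) library kit. The drugs were abemaciclib, palbociclib and ribociclib, 3 inhibitors of the cyclin-dependent kinases CDK4 and CDK6, at 0.3 or 3 µM, with abemaciclib also at 1 µM in MCF7. The libraries form 100 groups of line, drug, dose and time. Of these, 20 hold 2 libraries (abemaciclib 3 µM in every line, and the controls and every abemaciclib dose in MCF7) and 80 hold 1.

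The deposited values are log2 RPKM (reads per kilobase of gene, scaled to the reads of the library) made by the authors on build hg19, per the submitters' processing notes. The counting tool, its strand setting and the annotation release are not stated. The base and pseudocount were settled from the values: read as log2(RPKM + 1), 672 of 7395 low genes shared a single ratio between 2 libraries, as whole reads do, against 8 with base e and 5 with base 10. The table holds 49885 Ensembl gene identifiers, of which 45444 (91.1%) have a symbol in the reference gene names or in GENCODE. No annotation of hg19 was at hand, so no coordinates are given. A check list of 9 mitochondrially encoded genes could not be used, since 0 of them matched a gene in the table.

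Total read counts were not used here, so absolute depth is unknown. Relative depth came from what 1 read is worth in genes with RPKM under 2. It spanned 0.426 to 1.989 of the median among the libraries of the other 6 lines, without the failed HS578T control, and 0.251 to 1.19 among the 24 MCF7 libraries. The shallowest were MCF7 abemaciclib 3 µM at 24 h replicate 2 (0.251) and replicate 1 (0.424), and HS578T abemaciclib 3 µM at 6 h replicate 2 (0.426). Between 2 control libraries outside MCF7, or between 2 of MCF7, 440 to 825 low genes shared the commonest ratio of their values, as whole reads over 1 set of gene lengths give, but only 4 to 6 did between an MCF7 library and another. The MCF7 libraries thus appear to have been scaled with other gene lengths than the rest, so MCF7 levels are not compared with those of other lines. Differences within a line are little affected except for low genes, where the added pseudocount weighs differently with another gene length. Between replicate libraries the SD of the log2 difference was 0.91 to 1.06 outside MCF7 and 0.51 to 0.85 in MCF7.

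The HS578T control at 24 h had a value above 0 for 706 genes, while the next lowest library had 20844. It was left out, because it held values for fewer than 10000 genes. This departs from the design written before the data were examined: comparisons with control at 24 h cover 6 lines, HS578T has no 24 h comparison of its own, and BT549 is set against 5 other lines. Kept, it gave 16914 genes past the threshold for HS578T with abemaciclib 3 µM at 24 h (16297 higher, 617 lower), 15116 with palbociclib (14497 higher, 619 lower) and 15498 with ribociclib (14878 higher, 620 lower).

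Genes with RPKM of at least 1 in at least 8 libraries were kept, which left 28235. The MCF7 fit kept the 22061 genes with RPKM of at least 1 in at least 2 of its 16 libraries. Fold changes are differences of log2(RPKM + 1), which understate the change of low genes. All tests used limma 3.58.1 in R 4.3.3 with a variance trend and robust moderation, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The p-values measure only the spread between these samples. Across lines, replicate libraries of a line were averaged and the line was the block, so each line counts once (n = 7, or 6 at 24 h against control). The MCF7 fit used 16 libraries with 8 residual degrees of freedom. The fit of single lines used 119 libraries with 20 residual degrees of freedom. All of those degrees come from replicated groups, so groups of 1 library are assumed to vary like them. Of the 20, 8 come from MCF7, whose replicates differed less than those of the other lines. The errors for single lines other than MCF7 may therefore be understated. The same fit tested the effect in BT549, widely known to lack functional pRB, minus the mean effect in the other lines.

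The 16 gene lists, the rule for named genes, and the tests and comparisons other than those named next were fixed before the data were examined. Single lines were planned at 24 h only, so their comparisons at 6 h are additions. Camera was planned for comparisons across lines only, so its use in MCF7 and in single lines is an addition too. Of 483 list and check members, 464 matched an identifier. The rule took up to 10 genes higher and 10 lower, by mean log2 change, among those past the threshold with 1 sign in all lines, for 3 µM with control and for abemaciclib with either other drug at 3 µM; up to 3 and 3 elsewhere; 11 genes always; and for each list the members past the threshold with the largest change. Clone names and entries without a symbol were counted, not named. Lists were tested with camera (preset correlation 0.01, adjusted over 16 lists), again with an estimated correlation, and by an exact sign-flip permutation test over lines, whose smallest two-sided p is 0.015625 with 7 lines and 0.03125 with 6. The 95% intervals of list means over lines are the values that this exact test does not reject.

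On simulated data, the fit over 7 lines recovered 46.3%, 79.1% and 87.9% of genes changed 1.5-, 2- and 4-fold (67, 67 and 66 genes), with 9 false among 151 calls. Over 6 lines it recovered 38.8%, 73.1% and 89.4%, with 10 false of 144. Both runs over lines took their spread from palbociclib against ribociclib at 0.3 µM and 6 h, where 0 genes passed. Each changed gene was shifted by the same amount in every line. Recovery was not simulated for drug against control, so these percentages do not carry over to comparisons with more spread between lines. The MCF7 fit recovered 14.9%, 38.8% and 95.5%, with 9 false of 108. The fit of 1 library against 1 recovered 7.46%, 28.4% and 59.1%, with 6 false of 69.

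Alternatives in that first plan were a pseudocount of 0.1, no filter on low values, median-ratio rescaling of libraries (8352 genes behind the factors), each line or replicate left out, 1 fit over all conditions of a time, no line block, a replicate block in MCF7, an estimated correlation and fry. The fit over all conditions assumes 1 spread over lines for every drug and dose. The main tests fitted each comparison alone because that spread should differ between drugs. Chosen after seeing the data were a minimum mean log2 value of 4 (7370 genes), and, for single lines, genes at log2 of at least 1 in 90% of libraries (10918 genes, called widely expressed here). Leaving out the HS578T control at 24 h was decided then too. Keeping it, as the design had it, is given as an alternative. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.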

Results

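The data are RNA levels in 7 human breast cancer cell lines treated with abemaciclib, palbociclib or ribociclib, inhibitors of the kinases CDK4 and CDK6. The 120 libraries include 1 control per line and time, 2 in MCF7. Abemaciclib at 3 µM had 2 libraries per line and time, abemaciclib at 0.3 and 1 µM in MCF7 had 2, and each other line, drug, dose and time had 1. T47D and MCF7 had ESR1 (estrogen receptor) at 6.48 and 6.78 on the log2(RPKM + 1) scale, HCC1419 had ERBB2 at 12.63, and BT549 and HS578T had VIM (vimentin, a mesenchymal filament protein) at 10.39 and 11.64. RB1, which encodes pRB, the protein that CDK4 and CDK6 phosphorylate, had a median of 5.46 in BT549, a line widely known to lack functional pRB, and of 4.17 to 5.16 in the 5 lines other than MCF7. The comparisons ask what each drug changed, whether the drugs and doses differed, and how far the lines differed. Values are mean log2 changes ± SE over lines unless stated, with limma adjusted p-values.

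After 6 h of abemaciclib at 3 µM, single genes with roles in DNA replication and repair fell, the first 6 named here each lower in 7 of 7 lines; the E2F target list did not pass with an estimated correlation (adjusted p = 0.132). CCNE2 (ENSG00000175305), which encodes the S-phase cyclin E2, fell by 2.70 ± 0.33 (adjusted p = 0.0148). CLSPN (claspin, replication checkpoint) fell 3.99-fold. DTL changed by -1.95 ± 0.28, EXO1 by -1.93 ± 0.33, MCM10 (replication origin firing) by -1.72 ± 0.22 and BRCA2 (DNA repair) by -1.71 ± 0.25. HEXIM1 (ENSG00000186834) and MEPCE, both of the complex that holds the transcription kinase P-TEFb inactive, changed by -1.62 ± 0.24 and -1.98 ± 0.41. POLR2A, the largest subunit of RNA polymerase II, changed by -1.10 ± 0.19. In all, 785 genes passed the threshold, 315 higher and 470 lower (330 and 328 after median-ratio rescaling), of which 51 and 145 changed at least 2-fold. Other genes named by the rule were lower for PPP1R10 (-1.78), SRSF7 (-1.72) and MIR25 (-1.75), which lies in an intron of MCM7. Higher were GUCA1B (1.98), RAPSN (1.86), SLC22A1 (1.64) and C4orf48 (1.57 ± 0.25). The same rule named ADAMTSL4-AS1 (2.06 ± 0.24), ADAMTSL4-AS2 (1.76), BCAR3-AS1 (1.70), MIR663AHG (4.09 ± 0.73) and the pseudogenes LEFTY3P (2.44) and RPL32P29 (1.86), whose counts are uncertain because the strand setting of the counting is not stated and pseudogenes share sequence with their parents.

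By list, 25 of the 49 E2F target and G1/S genes fell at 3 µM and 6 h, 40 adjusted over the list alone. The list mean was -0.93 (SD 0.32, 7 of 7 lines lower, 95% interval from -1.16 to -0.61, exact sign-flip p = 0.0156, adjusted 0.0357). Of the 44 G2/M genes, 8 fell, 41 adjusted over the list alone, among them KIF11 (spindle motor, -1.41 ± 0.24), NCAPG (-1.28), SPC25 (-1.18) and NUF2 (-0.84). In camera both lists passed with the preset correlation but not with an estimated correlation (adjusted p = 0.132 and adjusted p = 0.289). Of the 38 lysosome genes, 6 rose, 14 adjusted over the list alone, including the proteases CTSA (0.58 ± 0.07), CTSD (0.45) and CTSB (0.43) and the proton pump subunit ATP6V0D1 (0.37). The lysosome list mean was 0.23 (SD 0.15, 7 of 7 lines higher, adjusted p = 0.0547 with an estimated correlation). Of 32 ribosomal protein genes, 11 rose, 27 adjusted over the list alone, such as RPS15 (0.53), RPL13 (0.51) and RPL8 (0.45), with adjusted p = 0.329 with an estimated correlation. Of 19 genes of P-TEFb and RNA polymerase II kinases, 3 fell, and the list mean was -1.26 in MCF7, -1.19 in HS578T and between -0.24 and 0.03 in the other 5 lines.

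Among smaller groups at 3 µM and 6 h, RBL1 (a pRB relative, -1.18 ± 0.18), CDKN2C (a CDK4/6 inhibitor, -1.04) and CCND3 (-0.64) fell within the 18 tested cyclin D, CDK and inhibitor genes. JUNB rose (1.09 ± 0.21) and PIM1 fell (-1.53 ± 0.22) among 38 immediate early and short-lived transcripts. MVD (1.08 ± 0.20) and SREBF2 (0.35) rose among 25 cholesterol genes, FAS fell (-0.92) among 23 p53 targets, CALR rose (0.31) among 15 chaperones, TAPBP (0.43) and HLA-C (0.32) rose among interferon and antigen presentation genes, H2BC5 rose (0.77) among 14 histone genes, and NDRG1 fell (-0.49) while ALDOA rose (0.30) in the hypoxia and glycolysis list. No WNT target, estrogen response gene or ATF4 target passed, with smallest p for DKK1 (-1.50, adjusted p = 0.0516), MYB (-1.02, adjusted p = 0.11) and NUPR1 (0.63, adjusted p = 0.0502). Not passing either were CCNE1 (-1.45, adjusted p = 0.0539), MKI67 (1.99-fold lower, adjusted p = 0.0616), E2F1 (-0.93), CCND1 (0.37), CDKN1A (0.53), MYC (-0.23), RB1 (-0.31), CDK4 (0.16) and CDK6 (-0.32). The count of 785 rested on the full set of lines: it was 0 without BT20, 1 without HCC1419, 0 without HCC1806, 127 without HS578T, 179 without BT549, 329 without T47D and 416 without MCF7, and 504 or 451 with 1 replicate left out.

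Palbociclib at 0.3 µM also lowered single replication genes at 6 h, while the E2F target list did not pass with an estimated correlation (adjusted p = 0.110). CCNE2 changed by -2.05 ± 0.28, MCM10 by -1.68 ± 0.23, WDR76 by -1.58 ± 0.24 and CDK2 (the cyclin E partner) by -0.71 ± 0.11, while MEGF8 (1.52), C4orf48 (1.22) and the pseudogene ABHD17AP6 (1.00) rose. Early response genes rose too: JUND by 0.79 ± 0.13, ZFP36L1 by 0.59, JUNB by 0.59 and ZFP36 by 0.53, 8 of 38 in that list and 14 adjusted over the list alone, with a list mean of 0.23 in 7 of 7 lines (adjusted p = 0.0404 with an estimated correlation). There 10 of 49 E2F genes fell, such as E2F2 (-1.28 ± 0.19) and ORC1 (-1.21), and 1 of 44 G2/M genes, PRC1 (-0.34). With palbociclib at 3 µM, FEM1A (1.30 ± 0.10), A1BG (0.96), DDIT4 (0.94 ± 0.08, an mTORC1 inhibitor and ATF4 target), SCAND1 (0.78), IER5L (0.71), PTRH1 (0.67), RABAC1 (0.65), ABHD17A (0.63), PPDPF (0.51) and MIF (0.50) rose. DDX11 (-0.92), RFWD3 (-0.83), CCP110 (-0.69) and RFC3 (-0.60 ± 0.06, replication clamp loader) fell. With ribociclib, FANCL fell at 0.3 µM (-0.68 ± 0.05, adjusted p = 0.049) and BRCA2 at 3 µM (-0.82 ± 0.06, adjusted p = 0.0224). CCNE2 was at -2.35 with palbociclib 3 µM (adjusted p = 0.0961), -2.20 with ribociclib 3 µM (adjusted p = 0.185) and -1.95 with abemaciclib 0.3 µM (adjusted p = 0.0579), lower in 7 of 7 lines each time.

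The counts at 6 h were 194 genes with palbociclib 0.3 µM (111 higher, 83 lower), 17 with palbociclib 3 µM (13 higher, 4 lower, and 29 and 16 after rescaling), 1 with each ribociclib dose and 0 with abemaciclib 0.3 µM. After rescaling they were 78 with abemaciclib 0.3 µM (48 higher, 30 lower), 0 with ribociclib 0.3 µM and 1 with ribociclib 3 µM. As deposited, limma gave 3711 genes at an unadjusted p under 0.05 for abemaciclib 0.3 µM. With no filter on low values the counts were 0 and 8 with palbociclib 0.3 and 3 µM. With 1 fit over all conditions at 6 h, which pools their spread, they were 585 with abemaciclib 0.3 µM, 534 and 404 with palbociclib 0.3 and 3 µM and 71 and 205 with ribociclib. The E2F list mean was -0.83 with abemaciclib 0.3 µM, -0.82 and -0.92 with palbociclib 0.3 and 3 µM, and -0.64 and -0.85 with ribociclib. Adjusted over the list alone, 47, 46, 47, 44 and 46 of its 49 genes fell. With an estimated correlation these lists had adjusted p = 0.0850, 0.110, 0.171, 0.243 and 0.122. The G2/M means were smaller, at -0.32, -0.23, -0.25, -0.17 and -0.21. Without BT549 the counts were 177 with abemaciclib 0.3 µM, 224 and 166 with palbociclib 0.3 and 3 µM, and 65 with ribociclib 3 µM. Without BT20, HCC1419, HCC1806, HS578T or T47D these 5 counts were 0, and without MCF7 that with palbociclib 0.3 µM was 31.

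**Figure D1:**
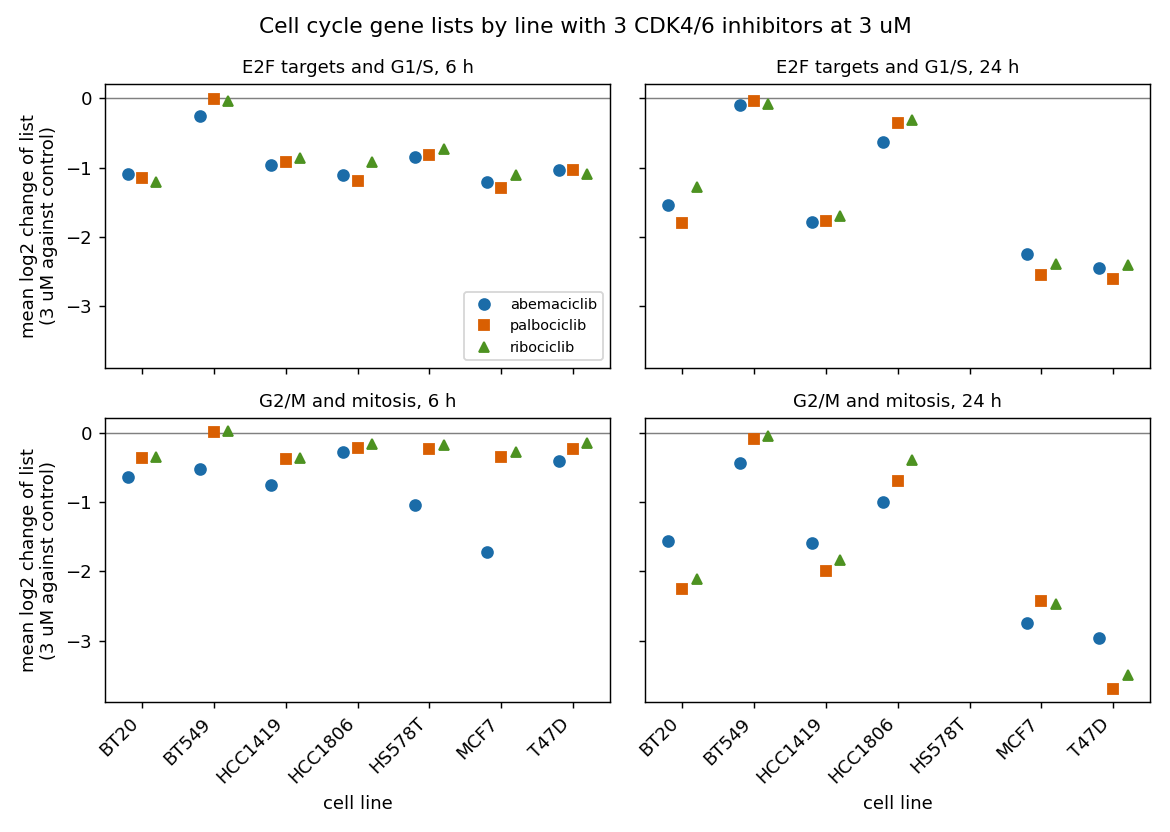
Mean log2 change from control of the E2F target and G1/S list and of the G2/M and mitosis list (vertical axes) in each line (horizontal axes) at 3 µM, at 6 and 24 h, with 1 marker per drug. At 24 h BT549 lay at -0.10, -0.04 and -0.07 on the E2F list, T47D at -2.45, -2.60 and -2.41, and HS578T has no value because its control failed.

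At 24 h, proliferation genes were lower in most lines, and few single genes passed where each comparison was fitted alone. MKI67 (ENSG00000148773), the proliferation marker Ki-67, had means of -2.02 and -2.24 with abemaciclib 0.3 and 3 µM, -2.14 and -2.14 with palbociclib, and -0.94 and -2.14 with ribociclib. CCNE2 had means of -2.28, -2.45, -1.94, -2.44, -0.66 and -2.19 in the same order. The E2F list had means of -1.26, -1.46 (SD 0.92), -1.24, -1.52, -0.50 and -1.36, and the G2/M list of -1.58, -1.72, -1.75, -1.87, -0.97 and -1.73, each lower in 6 of 6 lines (exact sign-flip p = 0.0312, the smallest that 6 lines allow). Adjusted over the list alone, 44, 45, 44, 48, 32 and 49 E2F genes fell, and 44 of 44 G2/M genes in each of the 6 comparisons. With an estimated correlation both lists had adjusted p = 0.257, 0.241, 0.298, 0.317, 0.209 and 0.403. The lysosome list was at 0.42 with abemaciclib 3 µM (SD 0.15, 6 of 6 lines higher, 19 of 38 adjusted over the list alone, adjusted p = 0.0654 with an estimated correlation), with CTSA at 0.71 ± 0.10 (adjusted p = 0.0999). The histone list was at 0.61 (adjusted p = 0.157 with an estimated correlation). DDIT4 was at 1.28 ± 0.19 (adjusted p = 0.0999), CDKN1A at 1.41 ± 0.82 and CCND1 at 0.62 ± 0.18, none of them past the threshold.

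Across 6 lines at 24 h, 2 genes passed with abemaciclib 3 µM: MIR3687-2, which shares sequence with the ribosomal RNA precursor, rose by 6.52 ± 0.37, and SNORA22B (a small nucleolar RNA) changed by -1.95 ± 0.14. Limma gave 0 genes in the other 5 comparisons at 24 h, with 3904 (abemaciclib 0.3 µM), 4375 and 3724 (palbociclib 0.3 and 3 µM) and 2844 and 3455 (ribociclib) at an unadjusted p under 0.05. Without MCF7 the count with abemaciclib 3 µM was 216. The counts depended on fitting each comparison alone, and those of the pooled fit on equal spread for every drug and dose. With 1 fit over all conditions at 24 h, which pools their spread, they were 896 and 4067 with abemaciclib 0.3 and 3 µM, 1290 and 978 with palbociclib and 8 and 691 with ribociclib. The p53 target list, at 0.38 (3 of 6 lines higher), passed the preset test (adjusted p = 0.0129) but not with an estimated correlation (adjusted p = 0.656), and without MCF7 its preset adjusted p was 0.9 with the opposite direction.

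From 6 to 24 h at 3 µM, the G2/M list mean over 6 lines moved by -0.99 (SD 0.87) with abemaciclib, -1.61 (SD 1.21) with palbociclib and -1.51 (SD 1.24) with ribociclib, in 5, 6 and 6 lines (exact sign-flip p = 0.0625, 0.0312 and 0.0312, adjusted 0.333, 0.25 and 0.5). The E2F list mean moved by -0.51, -0.58 and -0.49 (exact sign-flip p = 0.188, 0.156 and 0.156). None of these passed after adjustment, and the 2 lists were not tested against each other.

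Compared directly at 3 µM and 6 h, abemaciclib raised FASN (fatty acid synthase) and EEF2 (translation elongation) over both other drugs. FASN differed by 0.73 ± 0.05 from palbociclib (adjusted p = 0.0201) and by 0.68 ± 0.07 from ribociclib (adjusted p = 0.0408), and EEF2 by 0.41 ± 0.04 and 0.47 ± 0.03. ADAMTSL4-AS1, with the strand caveat above, differed by 2.22 ± 0.19 from palbociclib. Against ribociclib, MAFG (1.01), MIF (0.66), PFN1 (profilin, 0.62), ATP6V0C (lysosomal proton pump, 0.58) and CTSA (0.57) were higher with abemaciclib. WDR48 (-1.32), SRSF3 (splicing factor, -1.28), TRMT61B (-1.27), HEATR3 (-1.10), CUTC (-0.95), RAB3GAP1 (-0.91) and DNAJA1 (-0.76) were lower. The counts were 3 (3 higher) against palbociclib and 14 (7 higher, 7 lower) against ribociclib. After median-ratio rescaling they were 0 and 10 (5 higher, 5 lower), and EEF2 passed against neither drug and FASN against ribociclib alone. Other alternatives went both ways. Against ribociclib the count was lower with a pseudocount of 0.1, and 1 with no filter on low values. Without a block for the cell line both counts were 0. With a mean log2 value of at least 4 they were 200 and 212. With 1 fit over all conditions at 6 h, which pools their spread, they were 4072 and 4474. The spread was not equal, so the pooled fit can understate the error for abemaciclib. On the G2/M list lines ran from -1.72 to -0.28 with abemaciclib 3 µM against control, and from -0.39 to 0.01 with palbociclib 3 µM. HEXIM1 was at -1.51 ± 0.21 (adjusted p = 0.0933) and -1.55 ± 0.21 (adjusted p = 0.073), lower in 7 of 7 lines. The E2F list did not differ detectably: abemaciclib minus palbociclib was -0.01 (95% interval -0.13 to 0.08), abemaciclib minus ribociclib -0.08 (-0.19 to 0.05) and palbociclib minus ribociclib -0.07 (-0.19 to 0.05). G2/M genes were lower with abemaciclib than with palbociclib by -0.51 (-0.95 to -0.17, 20 of 44 adjusted over the list alone, adjusted p = 0.529 with an estimated correlation) and than with ribociclib by -0.56 (-0.99 to -0.21, adjusted p = 0.548 with an estimated correlation). Against control, the means with abemaciclib and palbociclib lay furthest apart in MCF7 (-1.72 and -0.36) and HS578T (-1.04 and -0.23), and closest in HCC1806 (-0.28 and -0.21). In MCF7 and HS578T widely expressed genes as a whole also fell with abemaciclib (medians -0.52 and -0.36). Without T47D the 2 counts were 4 and 4, and without BT20, BT549, HCC1419, HS578T or MCF7 both were 0.

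Palbociclib and ribociclib differed little at 3 µM and 6 h. Immediate early genes were higher with palbociclib by 0.14 (0.11 to 0.19, 7 of 7 lines, 8 of 38 adjusted over the list alone, adjusted p = 0.0437 with an estimated correlation), with JUNB at 0.34 ± 0.06 (adjusted p = 0.699). Limma gave 0 genes, and 1723 at an unadjusted p under 0.05. At 0.3 µM and 24 h ribociclib moved the cell cycle list means less than the others did, though the G2/M differences did not pass with an estimated correlation. Its E2F list lay above that of palbociclib, the difference palbociclib minus ribociclib being -0.75 (-1.22 to -0.15, 45 of 49 adjusted over the list alone) and abemaciclib minus ribociclib -0.74 (-1.38 to -0.15, 43 of 49). The G2/M differences were -0.82 (-1.24 to -0.32) and -0.62 (-1.04 to -0.22), with adjusted p = 0.219 and adjusted p = 0.243 with an estimated correlation. Abemaciclib minus palbociclib was 0.01 (-0.22 to 0.18) on the E2F list. TEX30 was the 1 gene past the threshold between palbociclib and ribociclib (-0.79 ± 0.06, adjusted p = 0.0477), and it was lost with any 1 line left out. Limma gave 0 genes for abemaciclib against palbociclib (1952 at an unadjusted p under 0.05) and against ribociclib (2523).

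At 3 µM and 24 h the lysosome list was higher with abemaciclib than with palbociclib by 0.34 (0.16 to 0.50, 16 of 38 adjusted over the list alone, 7 of 7 lines, adjusted p = 0.225 with an estimated correlation) and than with ribociclib by 0.32 (0.15 to 0.51, 15 of 38, 7 of 7 lines, adjusted p = 0.0954 with an estimated correlation). TPP1, a lysosomal peptidase, was at 0.75 ± 0.13 against palbociclib (adjusted p = 0.396) and CTSA at 0.57 ± 0.09 against ribociclib (adjusted p = 0.277). The E2F list differed by 0.22 (-0.15 to 0.72) between abemaciclib and palbociclib, by 0.03 (-0.25 to 0.37) between abemaciclib and ribociclib and by -0.19 (-0.40 to -0.02) between palbociclib and ribociclib. Limma gave 0 genes in these 3 comparisons, with 2667, 2908 and 1861 at an unadjusted p under 0.05. At 0.3 µM and 6 h it also gave 0, with 2193, 2213 and 1886. The 0 counts depended on fitting each comparison alone, and the counts of the pooled fit on equal spread for every drug and dose. With 1 fit over all conditions of a time, which pools their spread, abemaciclib at 3 µM and 24 h differed from palbociclib in 1974 genes and from ribociclib in 2408.

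Raising the dose from 0.3 to 3 µM moved cell cycle genes most with ribociclib at 24 h. There the E2F list mean changed by -0.85 (-1.41 to -0.16, 7 of 7 lines, 45 of 49 adjusted over the list alone) and the G2/M list by -0.79 (-1.27 to -0.21, 43 of 44), with adjusted p = 0.185 with an estimated correlation for both. The matching E2F changes were -0.29 (-0.49 to -0.05, 16 of 49) with palbociclib and -0.08 (-0.33 to 0.29) with abemaciclib. With abemaciclib at 24 h the lysosome list rose with dose by 0.27 (0.12 to 0.37, 7 of 7 lines, 6 of 38 adjusted over the list alone, adjusted p = 0.027 with an estimated correlation). With abemaciclib at 6 h the G2/M list changed by -0.45 (-0.79 to -0.16) and the P-TEFb list by -0.42 (-1.08 to -0.06), neither past the threshold with an estimated correlation (adjusted p = 0.492 and adjusted p = 0.657), with HEXIM1 at -1.17 ± 0.17 (adjusted p = 0.188). Limma gave 0 genes in all 6 dose comparisons, with 3569, 2256 and 1614 at 6 h (abemaciclib, palbociclib, ribociclib) and 2178, 2858 and 2549 at 24 h at an unadjusted p under 0.05. These counts depended on fitting each comparison alone, and those of the pooled fit on equal spread for every drug and dose. With 1 fit over all conditions of a time, which pools their spread, 2315 and 675 genes passed between the abemaciclib doses at 6 and 24 h.

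In MCF7, abemaciclib lowered replication and mitosis genes at every dose and raised p53 targets at 1 and 3 µM at 24 h. At 0.3 µM and 24 h RRM2 (ribonucleotide reductase) fell by 4.32 ± 0.09, CCNE2 by 4.22 ± 0.24 and CDC45 by 3.44 ± 0.26. At 3 µM and 24 h SMC4 (condensin) changed by -5.16 ± 0.19 and MKI67 by -4.44 ± 0.14. CDKN1A, which encodes the CDK inhibitor p21, changed by 0.78, 3.60 and 2.50 at 6 h (0.3, 1 and 3 µM), and by -0.06 (not past the threshold), 2.33 and 6.12 ± 0.09 at 24 h. At 3 µM and 24 h GDF15 (4.80 ± 0.17), BTG2 (4.29 ± 0.10) and AEN (4.20 ± 0.11), all p53 targets, rose as well. The p53 list mean was 2.15 (17 of 23 higher, 1 lower, adjusted p = 0.0383 with an estimated correlation). It was 1.12 at 1 µM and 6 h (15 higher, adjusted p = 0.0532 with an estimated correlation), 0.80 at 1 µM and 24 h (adjusted p = 0.0493 with an estimated correlation), and 0.25 at 3 µM and 6 h (8 higher, 7 lower, adjusted p = 0.315 with an estimated correlation, and 0.81 in each replicate after rescaling). HEXIM1 changed by -1.09, -2.49 and -2.88 at 6 h, and AURKA (mitotic kinase) by -4.66 ± 0.16 at 3 µM.

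The E2F list mean in MCF7 was -1.18, -1.35 and -1.21 at 6 h and -2.09, -1.52 and -2.25 at 24 h (0.3, 1 and 3 µM). The G2/M mean was -0.55, -1.50 and -1.72, then -1.89, -1.54 and -2.75. All 12 passed with an estimated correlation, the largest adjusted p being 0.0267. At 3 µM and 6 h rescaling gave -0.68 and -0.70 for the E2F list and -1.19 and -1.17 for the G2/M list in the 2 replicates. Ribosomal protein genes rose, 32 of 32 at 1 and 3 µM at 6 h. With an estimated correlation that list had adjusted p = 0.156, 0.0532 and 0.0318 at 6 h and 0.0474, 0.204 and 0.0597 at 24 h. The P-TEFb list fell at 3 µM and 6 h (-1.26, 13 of 19 lower, adjusted p = 0.0494 with an estimated correlation, and -0.78 and -0.73 in the replicates after rescaling), with MEPCE at -4.17 ± 0.13. Its mean at 3 µM and 24 h, -0.60, turned positive after median-ratio rescaling (0.03 and 0.22 in the 2 replicates). CCND1 changed by 1.28 at 0.3 µM and 6 h and by 0.88 at 1 µM and 24 h; at 3 µM and 6 h it was -0.32 as deposited and 0.28 rescaled, and CDK4 at 1 µM and 6 h went from -0.00 to 0.37. E2F1 changed by -1.35, -1.02 and -0.33 at 6 h (the last not past the threshold, and 0.25 rescaled) and by -2.49, -1.98 and -0.79 at 24 h (the last -0.03 rescaled). Other genes named by the rule were POLA2 (-3.50), ARHGEF39 (-4.06), PRR15L (-4.47) and, higher, GUCA1B (2.82), CLSTN3 (1.98) and RASD1 (3.20).

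The MCF7 counts were 654 (250 higher, 404 lower), 6905 (2141, 4764) and 7842 (1834, 6008) at 6 h and 1035 (375, 660), 2560 (1193, 1367) and 11520 (3282, 8238) at 24 h for 0.3, 1 and 3 µM. At 3 µM the median change of the 10918 widely expressed genes was -0.52 at 6 h and -0.78 at 24 h, so E2F, G2/M and p53 changes were also taken relative to it by rescaling. The rescaled counts were 634 (364 higher, 270 lower), 6337 (3685, 2652) and 7719 (4296, 3423) at 6 h, and 1151 (605, 546), 2353 (1095, 1258) and 10469 (5879, 4590) at 24 h. Rescaled at 3 µM and 24 h, the 2 replicates gave -1.57 and -1.67 for the E2F list, -1.97 and -2.25 for the G2/M list and 3.04 and 2.85 for the p53 list. Leaving out 1 library lowered the counts to between 164 and 184 (0.3 µM, 6 h), 4594 and 5207 (1 µM, 6 h), 545 and 674 (0.3 µM, 24 h) and 1282 and 1557 (1 µM, 24 h).

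**Figure D2:**
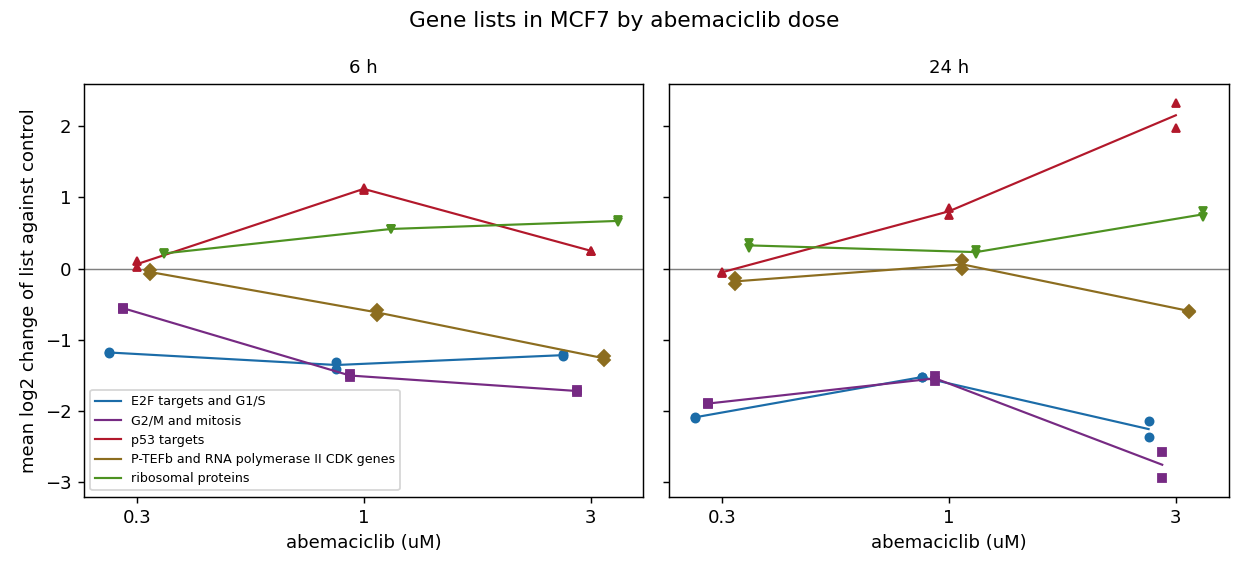
Mean log2 change from control of 5 gene lists in MCF7 (vertical axis) by abemaciclib dose in µM (horizontal axis) at 6 and 24 h. Points are the 2 replicates and lines their means; at 3 µM and 24 h the p53 replicates lie at 2.33 and 1.97, and the P-TEFb list, at -0.60, turns to 0.03 and 0.22 in the replicates after rescaling.

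In single lines at 3 µM and 24 h, RRM2 was among the genes that fell most. With palbociclib it changed by -5.92 ± 0.19 in T47D, -5.65 in MCF7, -4.47 in BT20 and -3.51 in HCC1419. With abemaciclib it changed by -4.83 ± 0.17 in T47D, -3.65 in HCC1419, -3.55 in BT20 and -1.39 in HCC1806. MKI67 changed by -3.81, -5.15 and -4.55 in T47D (abemaciclib, palbociclib, ribociclib), where CCND1 rose by 1.30, 0.91 and 1.21. In HCC1806 the changes were smaller, with E2F list means of -0.64, -0.36 and -0.31, while abemaciclib raised CDKN1A by 1.62 ± 0.22 and GDF15 by 2.90 ± 0.44. E2F list means in the same drug order were -1.53, -1.80 and -1.28 in BT20, -1.78, -1.77 and -1.70 in HCC1419, -2.25, -2.55 and -2.40 in MCF7 and -2.45, -2.60 and -2.41 in T47D, and all of these passed with an estimated correlation. In 2 libraries, HCC1419 and HCC1806 with abemaciclib at 24 h (replicate 1), SPARC and COL1A2, matrix genes abundant in HS578T and BT549, were high, SPARC at 6.55 and 6.88 against medians of 0.15 and 0.04 in the other libraries of those lines at 24 h. The counts for abemaciclib were 1475 in BT20, 833 in BT549, 1174 in HCC1419, 1243 in HCC1806, 11237 in MCF7 and 1897 in T47D. For palbociclib they were 712, 109, 547, 172, 935 and 1274, and for ribociclib 688, 53, 629, 153, 703 and 938. Among the 10918 widely expressed genes the counts were 1107, 592, 974, 903, 7871 and 1528 with abemaciclib, 494, 3, 398, 20, 882 and 1004 with palbociclib and 422, 6, 425, 3, 713 and 641 with ribociclib. Abemaciclib had 2 treated libraries per line and the other drugs 1, so the power to call genes differed. The counts therefore do not rank the drugs. With no filter on low values the palbociclib and ribociclib counts rose in BT20, BT549, HCC1419 and HCC1806. In the lines other than MCF7, most of the genes with the largest changes were small RNA and pseudogene entries.

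BT549 kept MKI67 and the E2F list near control with all 3 drugs at 3 µM and 24 h. MKI67 was at -0.18 ± 0.21, -0.06 ± 0.25 and -0.00 ± 0.25 (abemaciclib, palbociclib, ribociclib) and the E2F list at -0.10, -0.04 and -0.07. The G2/M list was at -0.43, -0.09 and -0.04. BT549 minus the mean of 5 other lines was 2.48, 2.49 and 2.57 for MKI67, 2.63, 2.95 and 2.53 for CCNE2 and 1.78, 2.10 and 1.77 for E2F1. It was 1.63, 1.78 and 1.55 for the E2F list and 1.54, 2.13 and 2.02 for the G2/M list, all past the threshold with an estimated correlation. Abemaciclib nonetheless changed 833 genes in BT549. Interferon response genes rose, 21 of 33, with a list mean of 1.31: IFI44L by 3.83 ± 0.24, MX1 by 2.94 ± 0.49, OAS2 by 2.93 and OAS3 by 2.75. ATF4 targets rose, 13 of 28, such as PCK2 (2.22) and ASNS (1.37), and 13 of 25 cholesterol genes fell, such as HMGCS1 (-1.96 ± 0.17), MVD (-1.79) and INSIG1 (-1.54). H2AC6 rose by 2.53, HEXIM1 changed by -1.24 ± 0.18, and 5 of 44 G2/M genes fell, including TTK (-0.90) and NUSAP1 (-0.74). With palbociclib the interferon list was at 0.65 (adjusted p = 0.0013 with an estimated correlation, IFI44L at 1.93 ± 0.28), and with ribociclib at 0.45 (adjusted p = 0.0599 with an estimated correlation).

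The genes whose change in BT549 differed from that in the 5 other lines numbered 1280 with abemaciclib (911 higher, 369 lower), 476 with palbociclib (368, 108) and 366 with ribociclib (301, 65). With the failed HS578T control kept they were 5529, 4986 and 4664. Against the other lines the interferon list differed by 1.36, 0.56 and 0.34 (adjusted p = 4.2e-05, adjusted p = 0.015 and adjusted p = 0.42 with an estimated correlation). The mean of the 5 other lines included MCF7, where 11237 genes passed with abemaciclib. The tests of BT549 against the other lines took their spread from replicate libraries, not from differences between lines. BT549 had 1 control library at 24 h, so all its values at that time share it, and 1 line says nothing about other lines without pRB.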

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

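The tests of the explanations weighed below were chosen after the result was seen, except the share held by abundant genes and the share of genes below control in the deeper library, which were set earlier.

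BT549 stayed near control on the E2F list while other lines moved. Its G2/M list was at -0.53 at 6 h and -0.43 at 24 h with abemaciclib. HCC1806 also moved little on the E2F list at 3 µM and 24 h with palbociclib (-0.36) and ribociclib (-0.31). With those drugs BT20, HCC1419, MCF7 and T47D were at -1.28 or lower. The difference of BT549 from the mean of 5 other lines at 3 µM and 24 h passed a test on the difference itself on both cell cycle lists. For abemaciclib, palbociclib and ribociclib it was 1.63, 1.78 and 1.55 on the E2F list and 1.54, 2.13 and 2.02 on the G2/M list. The genes that differed numbered 1280, 476 and 366. That test took its spread from replicate libraries, not from differences between lines, and no other line was put through it. It therefore cannot tell whether BT549 lies outside the spread of lines. At 6 h BT549 lay apart from the other lines on the E2F list with each drug (-0.25, -0.016 and -0.040). With abemaciclib BT549 also differed on interferon genes (1.36), ATF4 targets (0.60), histone genes (0.69), p53 targets (-0.56), cholesterol genes (-0.84) and lysosome genes (-0.16). The p53 difference rests on MCF7: that list was at 2.15 in MCF7, -0.09 in BT549 and between -0.17 and 0.27 in BT20, HCC1419, HCC1806 and T47D. The number of genes also takes in MCF7, where 11237 genes passed with abemaciclib. With palbociclib it differed on interferon genes (0.56), ATF4 targets (0.37) and the cyclin D, CDK and inhibitor list (0.45), and with ribociclib on that last list (0.36).

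Missing drug in BT549 was weighed as a technical explanation. With abemaciclib 592 widely expressed genes changed in BT549, which argues against libraries that received no drug. With palbociclib 3 lists passed in camera with an estimated correlation and 3 widely expressed genes changed, and with ribociclib 0 lists passed with an estimated correlation and 6 of those genes changed. Each of these 2 drugs had 1 library against 1 control, which excludes nothing, so a library without the drug cannot be told apart there. The depth of the BT549 libraries was 0.943 of that of the other lines except MCF7, which argues against shallow libraries. The smallest E2F change of 6 lines lay in BT549 with 3 of 3 drugs, which restates the pattern, so a lack of functional pRB stays open; RB1 mRNA had a median of 5.46 in BT549 and 4.17 to 5.16 in the 5 lines other than MCF7, and pRB protein was not measured.

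After 6 h of abemaciclib at 3 µM, more genes fell than rose in MCF7 (6008 against 1834) and HS578T (4341 against 1141), while after median-ratio rescaling 3423 fell and 4296 rose in MCF7 and 2898 fell and 2613 rose in HS578T. In the deeper library of each pair 67.8% (HS578T) and 72.2% (MCF7) of widely expressed genes lay below the control, which argues against shallow libraries as the cause. The 500 genes most abundant in the control took 7.50 points more of the total in HS578T and 13.0 points more in MCF7, so a few abundant genes taking more of each library may explain part of it and cannot be told apart from a fall of most other RNAs. Immediate early and short-lived transcripts lay -0.74 from the median of all tested genes in HS578T and 0.08 from it in MCF7. That median, -0.02 and -0.08, takes in low genes. Widely expressed genes had medians of -0.36 in HS578T and -0.52 in MCF7, against list means of -0.76 and -0.004. In MCF7 the list (12 higher, 13 lower) lay above them, which argues against a general loss of short-lived transcripts there. In HS578T such a loss stays open.

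The p53 target list in MCF7 with abemaciclib 3 µM at 24 h, at 2.15, lay far above the other 5 lines. The deeper library alone gave 2.33, which argues against replicate 2 alone as the source, though both libraries were shallow (relative depth 0.424 and 0.251), and median-ratio rescaling gave 2.94, which argues against the scaling to library totals. No biological explanation was tested.

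Further values lay far from the other lines of their group: immediate early genes in HS578T at 6 h (-0.76) and in MCF7 at 24 h (0.57), p53 targets in HS578T at 6 h (-0.79) and ribosomal protein genes in MCF7 at 24 h (0.76), all with abemaciclib. Interferon genes in BT549 at 24 h were at 1.31 with abemaciclib and 0.65 with palbociclib. With palbociclib the p53 list in T47D was at -0.22 at 24 h and the hypoxia list in HS578T at -0.27 at 6 h. With ribociclib the estrogen response list was at -0.12 in HS578T at 6 h. With ribociclib at 24 h HCC1419 lay apart on the P-TEFb (-0.25), lysosome (-0.079), estrogen response (-0.22) and hypoxia lists (-0.21). Those HCC1419 values come from 1 library, whose log2 factor in median-ratio rescaling was -0.015 against 0.139 in its control. For HS578T with abemaciclib at 6 h the factors were -0.42 and -0.39 against -0.03. The list values here are as deposited, so a shift of most genes in these libraries is not separated from them. In the HS578T control at 24 h 706 genes had a value above 0. Of 98 groups tested 18 held a value this far out, 1 of them the failed HS578T control. Chance gives about 1 in 20 only for independent groups. These groups share lines, controls and libraries, so the 18 cannot be read as an excess over chance.

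Other sign patterns of the lines were fitted as a test of chance, with 64 patterns for 7 lines and 32 for 6. Against control at 6 h only the real pattern, 1 of 64, gave as many genes with abemaciclib 3 µM (785, highest other pattern 0). The same held for palbociclib 0.3 µM (194, highest other 1) and 3 µM (17, highest other 0). Between drugs it held for abemaciclib against ribociclib at 3 µM and 6 h (14, highest other 1). A share of 1 of 64 is the smallest that 7 lines allow, and it was not adjusted over the comparisons made. The real pattern thus stood apart from the others there, but chance is not excluded. For abemaciclib 3 µM against control at 24 h 1 of 32 patterns gave as many (2 genes, highest other 0), and for abemaciclib against palbociclib at 3 µM and 6 h 1 of 64 (3 genes, highest other 0). The comparisons with 1 gene were ribociclib against control at 6 h, with 2 of 64 patterns as large at 0.3 µM (highest other 1) and 1 of 64 at 3 µM (highest other 0), and palbociclib against ribociclib at 0.3 µM and 24 h, with 1 of 64 (highest other 0). Patterns other than the real one also gave 1 gene in several comparisons, so counts of 1 to 3 genes do not exclude chance over all the comparisons made. In the comparisons with 0 genes in limma all 64 patterns, or all 32 against control at 24 h, give as many by construction, so there the test says nothing about chance. Their highest other pattern gave 1 gene for abemaciclib and ribociclib 0.3 µM against control at 24 h, abemaciclib against ribociclib at 0.3 µM and 6 h, palbociclib against ribociclib at 3 µM and 6 h, abemaciclib against palbociclib at both doses and against ribociclib at 3 µM at 24 h, and the palbociclib and ribociclib doses at 24 h. For the other comparisons with 0 genes it gave 0.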

How the results depend on the processing

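The minimum mean log2 value of 4 and the limit to widely expressed genes were chosen after the data were seen, as was leaving out the HS578T control at 24 h. Keeping that control, as the design had it, is an alternative here. The other alternatives were chosen beforehand. Over all alternatives 378 of the counts of genes stayed within 1.5 times their value and 211 moved further. Of the named genes' values 5274 kept their side of the threshold, 622 lost and 106 gained the threshold and 2 changed direction, against 5903, 417, 137 and 9 for the lists. A change of direction was counted only where 1 of the 2 values passed; among values that never passed some changed direction too. The cause was not tested unless stated.

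Median-ratio rescaling gave 78 genes for abemaciclib 0.3 µM and 45 for palbociclib 3 µM at 6 h, and 0 for ribociclib 0.3 µM at 6 h, for abemaciclib against palbociclib at 3 µM and 6 h and for palbociclib against ribociclib at 0.3 µM and 24 h. It turned CDK4 at 1 µM (0.37) and CCND1 at 3 µM (0.28) positive in MCF7 with abemaciclib at 6 h. With a pseudocount of 0.1 the counts were 10 for palbociclib 3 µM at 6 h, 9 for abemaciclib against ribociclib at 3 µM and 6 h, 0 for palbociclib against ribociclib at 0.3 µM and 24 h and 108 for palbociclib in HCC1806.

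With a mean log2 value of at least 4, which left 7370 genes, the counts at 6 h were 537 and 1399 for abemaciclib 0.3 and 3 µM, 714 and 274 for palbociclib and 31 for ribociclib 3 µM. At 24 h they were 373 and 267 for abemaciclib and 987 and 120 for palbociclib. Abemaciclib differed at 3 µM and 6 h from palbociclib in 200 and from ribociclib in 212 genes, and the doses at 24 h in 30 for palbociclib and 1 for ribociclib. In MCF7 the counts were 3611 at 1 µM and 4196 at 3 µM at 6 h and 5453 at 3 µM at 24 h, with fewer genes tested. With no filter on low values the counts at 6 h were 245 for abemaciclib 3 µM, 0 and 8 for palbociclib 0.3 and 3 µM, 0 for ribociclib 0.3 µM, 1 for abemaciclib against ribociclib at 3 µM, and at 24 h 0 for palbociclib against ribociclib at 0.3 µM. BT549 then differed from the other lines in 2113, 1779 and 1745 genes (abemaciclib, palbociclib, ribociclib). Palbociclib gave 1200 in BT20, 523 in BT549, 1125 in HCC1419 and 866 in HCC1806, and ribociclib gave 1251, 536, 1495 and 987 there and 1680 in T47D. Among widely expressed genes palbociclib gave 3 in BT549 and 20 in HCC1806, and ribociclib 422 in BT20, 6 in BT549 and 3 in HCC1806.

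With 1 fit over all 7 conditions of a time, which pools their spread, the counts at 6 h were 585 and 5427 for abemaciclib 0.3 and 3 µM, 534 and 404 for palbociclib and 71 and 205 for ribociclib. At 24 h they were 896 and 4067, 1290 and 978, and 8 and 691. Between drugs it gave 4 for abemaciclib against ribociclib at 0.3 µM and 6 h. At 3 µM and 6 h it gave 4072 for abemaciclib against palbociclib, 4474 against ribociclib and 1 for palbociclib against ribociclib, and at 3 µM and 24 h 1974 and 2408 for abemaciclib against palbociclib and ribociclib. It gave 0 for palbociclib against ribociclib at 0.3 µM and 24 h. Between doses it gave 2315 and 675 for abemaciclib at 6 and 24 h and 1 and 1 for palbociclib. Without a block for the cell line the counts at 6 h were 2 for abemaciclib 3 µM, 0 and 0 for palbociclib 0.3 and 3 µM, 0 and 0 for ribociclib, 1 for abemaciclib against ribociclib at 0.3 µM, 0 and 0 for abemaciclib against palbociclib and ribociclib at 3 µM, and 1 between the palbociclib doses. At 24 h they were 1 for abemaciclib 3 µM and 0 for palbociclib against ribociclib at 0.3 µM; the differences between lines then entered the spread. With a replicate block in MCF7 the counts were 514, 6637 and 7708 at 6 h and 968, 2335 and 11343 at 24 h.

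Lists passed less often when the correlation between their genes was estimated. The E2F and G2/M lists then had adjusted p-values at 6 h of 0.0850 and 0.0998 (abemaciclib 0.3 µM), 0.132 and 0.289 (3 µM), 0.110 and 0.110 (palbociclib 0.3 µM), 0.171 and 0.171 (3 µM), 0.243 and 0.243 (ribociclib 0.3 µM) and 0.122 and 0.170 (3 µM). At 24 h both lists had 0.257 and 0.241 with abemaciclib 0.3 and 3 µM, 0.298 and 0.317 with palbociclib and 0.209 and 0.403 with ribociclib. In fry the G2/M list had 0.0543 with ribociclib 3 µM at 6 h. At 24 h both lists had 0.0682 with abemaciclib 0.3 µM, 0.0632 and 0.0564 with palbociclib 0.3 and 3 µM and 0.0557 and 0.114 with ribociclib.

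With the HS578T control at 24 h kept, the direction in camera changed for chaperones with abemaciclib 0.3 µM (adjusted p = 0.864) and ribociclib 0.3 µM (adjusted p = 0.714), the cyclin D, CDK and inhibitor list with ribociclib 0.3 µM (adjusted p = 0.396) and ATF4 targets with ribociclib 3 µM (adjusted p = 0.692). The count for abemaciclib 3 µM at 24 h was then 1, and BT549 differed from the other lines in 5529, 4986 and 4664 genes.

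Leaving out 1 line or replicate at a time gave from 0 to 177 genes at 6 h for abemaciclib 0.3 µM (177 without BT549), 0 to 504 for abemaciclib 3 µM, 0 to 224 and 0 to 166 for palbociclib 0.3 and 3 µM (highest without BT549), 0 to 1 for ribociclib 0.3 µM and 0 to 65 for ribociclib 3 µM (65 without BT549). At 24 h it gave 0 to 2 and 0 to 216 for abemaciclib 0.3 and 3 µM (216 without MCF7), 0 to 2 and 0 to 1 for palbociclib and 0 to 1 and 0 to 1 for ribociclib. Between drugs it gave 0 to 2 for abemaciclib against ribociclib at 0.3 µM and 6 h, 0 to 4 and 0 to 5 for abemaciclib against palbociclib and ribociclib at 3 µM and 6 h, 0 for palbociclib against ribociclib at 0.3 µM and 24 h, and 0 to 1 for abemaciclib against each other drug at 3 µM and 24 h. Between the palbociclib doses at 6 h it gave 0 to 1. For p53 targets at 24 h the adjusted p ran from 0.00133 to 0.89995 for abemaciclib 3 µM, 0.00153 to 0.497 against palbociclib, 0.000186 to 0.939 against ribociclib and 0.000593 to 0.372 between the abemaciclib doses, with the direction reversed without MCF7 in all 4. For ATF4 targets with abemaciclib against palbociclib at 3 µM and 24 h it ran from 0.00124, without HS578T, to 0.952, without abemaciclib replicate 2, both with the direction reversed.

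In MCF7, leaving out 1 library gave 164 to 184 genes at 0.3 µM and 4594 to 5207 at 1 µM at 6 h, and 545 to 674 and 1282 to 1557 at 24 h; the lone library is then assumed to vary like the other groups. In single lines, leaving out abemaciclib 3 µM replicate 1 or replicate 2 of every line at once gave, with abemaciclib, 2894 to 3232 in BT20, 2139 to 2956 in BT549, 2911 to 3125 in HCC1419, 3011 to 3102 in HCC1806, 3193 to 3208 in T47D and 4029 to 4485 for BT549 against the other lines. With palbociclib this gave 2471, 1501, 2323 and 1841 in the first 4 lines, 3082 to 3083 in T47D and 3118 to 3123 for BT549 against the others, and with ribociclib 2474, 1434, 2539, 1848, 2722 and 2944 in the same order. In these single-line fits the spread came from the replicates of MCF7 alone, assumed to hold for every line. Depth limits the genes at low values: libraries reached down to 0.251 of the median depth in MCF7 and 0.426 in the other lines.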

Other observations

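No test of an explanation is reported in this part; the entries of microRNA host regions and the libraries with high SPARC were looked up after other results were seen.

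With abemaciclib at 3 µM and 24 h the lysosome list mean lay above control in each line with a control, though in MCF7 its call depended on the fit. The mean was 0.50 in BT20, 0.29 in BT549, 0.44 in HCC1419, 0.49 in HCC1806, 0.21 in MCF7 and 0.61 in T47D, with adjusted p = 4.0e-05, 0.00057, 2.5e-06, 1.2e-05, 0.0068 and 3.0e-06 in camera with an estimated correlation in the fit of single lines. In the fit of MCF7 alone it did not pass (adjusted p = 0.0991 with an estimated correlation). GPNMB, a lysosomal membrane glycoprotein, rose by 3.12 in BT20, 3.43 in T47D, 1.99 in HCC1419 and 2.22 in MCF7. NEU1 (sialidase) rose by 1.45 in BT20, 1.65 in T47D, 1.23 in HCC1419, 1.51 in HCC1806 and 0.85 in BT549. In MCF7 9 of the 38 genes fell while 18 rose, and after median-ratio rescaling its list mean was 0.93 and 0.94 in the 2 replicates, above those of the other lines (up to 0.73 in a T47D replicate).

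ATF4 targets, the amino acid and stress response genes, went different ways at 6 h with abemaciclib 3 µM. These comparisons of single lines at 6 h were not in the plan. The list mean was 0.97 in BT549 (17 of 28 higher), 0.89 in HCC1806 (15), 0.79 in HCC1419 (17) and 0.46 in BT20 (7), all past the threshold with an estimated correlation, but -0.72 in HS578T (9 lower) and -0.50 in MCF7, which did not pass. After median-ratio rescaling the 2 replicates gave -0.36 and -0.42 in HS578T and -0.08 and 0.02 in MCF7. In T47D the replicates were at 0.14 and 0.18. With palbociclib at 6 h it was 0.76 in BT549 and 0.50 in HS578T, and with ribociclib 0.03 in BT549.

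The interferon list in BT549 at 24 h had means of 0.43 and 1.31 with abemaciclib 0.3 and 3 µM, -0.10 and 0.65 with palbociclib and 0.09 and 0.45 with ribociclib. At 6 h the values were 0.08 and -0.02, -0.32 and -0.22, and 0.04 and -0.09. All values at a time share 1 control library. The difference between doses was not tested.

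The entries MIR3687-2, MIR3648-2, MIR663AHG and MIR663B share sequence with the region of the 45S ribosomal RNA precursor, so their reads cannot be assigned to microRNA genes. With abemaciclib 3 µM at 6 h MIR3687-2 was at 7.11 ± 1.09 (6 of 7 lines higher, adjusted p = 0.0256), MIR3648-2 at 5.19 ± 0.94 (6 of 7, adjusted p = 0.0336), MIR663AHG at 4.09 ± 0.73 (7 of 7, adjusted p = 0.0329) and MIR663B at 3.47 ± 1.07 (adjusted p = 0.12). At 24 h MIR3687-2 was at 6.52 ± 0.37 (6 of 6, adjusted p = 0.00889), MIR663AHG at 3.05 (adjusted p = 0.126) and MIR3648-2 at 3.44 (adjusted p = 0.153). Palbociclib gave large means as well, none past the threshold: MIR3687-2 was at 3.84 and 3.94 at 6 h (0.3 and 3 µM, 5 of 7 lines higher each) and at 5.55 with 0.3 µM at 24 h (5 of 6, adjusted p = 0.129), and MIR663AHG at 1.77 and 1.47 at 6 h (7 of 7 each).

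In 4 libraries SPARC and COL1A2 both lay more than 3 log2 units above the median of the other libraries of their line and time. SPARC was at 6.55 against 0.15 in HCC1419 with abemaciclib 3 µM at 24 h (replicate 1) and at 6.88 against 0.04 in HCC1806 with the same treatment (replicate 1). It was at 7.33 against 0.54 in BT20 with ribociclib 3 µM at 6 h and at 8.46 against 3.12 in HCC1806 with palbociclib 3 µM at 6 h. COL1A2 was at 4.63, 4.75, 4.83 and 6.06 there, and VIM between 4.61 and 6.70. Median SPARC was 13.81 in HS578T and 12.17 in BT549.

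Check lists of marker genes gave PGR at 6.02 in T47D and GRB7 at 9.65 in HCC1419. Of the blood, endothelial and erythroid markers, those with a median above 1 in at least 1 line were CD68 (up to 6.16 in HS578T), CDH5 (up to 5.54 in BT20), HBA1 (1.92 in HCC1806, and 2.67 in MCF7, whose levels are not compared with those of other lines), CD14 (1.25 in HS578T), VWF (1.12 in HCC1419) and CD19 (1.07 in T47D).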
